A study of Arabidopsis thaliana with 10 samples.

How the data were processed

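Transcript levels were measured in roots of 20-day-old Arabidopsis seedlings on 10 Affymetrix arrays, 5 from the Col-0 wild type and 5 from mcu123, which the labels describe as a knockout of 3 MCU genes. MCU proteins are the pore subunits of the mitochondrial calcium uniporter. Per the labels' protocols, seedlings grew in sterile hydroponics under 16 h light at 21 °C and 8 h darkness at 17 °C. Roots were cut from the shoot and frozen at once, and each replicate was RNA pooled from several root systems. The labels do not say whether the replicates came from separate growth batches, so the p-values measure the spread between these pools.

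The deposited values are log2 intensities that the authors obtained with RMA, per the submitters' processing notes. RMA corrects the background, equalises the distribution of all arrays and summarises the probes of each feature. The deposited table held 27826 rows, each named by 1 locus code, and the sorted log2 values of the 10 deposited columns were identical, with a median of 4.30 on each array. The array model, the probe grouping, the software version and the genome build are not given in the sources used here. Values ran from 0.60 to 13.35 on the log2 scale. Joint quantile normalisation removes any shift shared by all genes, so a global change in transcript amount cannot be read from these values. No detection calls were available here, so a low value could not be separated from background, and the number of arrays limits the precision.

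Locus codes were matched to the RefSeq gene table of assembly TAIR10.1, which was used only for names and for the order of neighbouring genes. It held 27241 of the 27826 codes and gave 10556 of them a symbol other than the code. The names MCU1 to MCU6, MICU and JOX1 to JOX4 came from the gene lists and not from that table.

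Genes were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited values, a coefficient for genotype and no other term. Tests were two-sided, with Benjamini-Hochberg adjustment over all 27826 genes and a threshold of 0.05. No gene was dropped for low signal. A second count required a change of at least 2-fold. Adjusted p-values of genes below are from this limma fit. The fit was also run on simulated data with 27826 genes in 10 runs, with the spread of these arrays. In each run 200 genes were changed. The fit called 15.2% of genes changed by 0.5 on the log2 scale, 69.8% at a change of 1 and 91.8% at 1.5. Of its calls, 5.21% were false. These rates apply to that design and need not hold where fewer genes change or where genes vary together.

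The groups, the tests, 27 gene lists with 424 members and the rule for naming genes were fixed before the data were examined. All 424 members were on the array. The pathway lists covered mitochondrial calcium uptake, other calcium transport, the respiratory chain, the tricarboxylic acid cycle, alternative respiration, jasmonate synthesis, jasmonate signalling, touch, hypoxia, salicylic acid, abscisic acid, auxin, cytokinin, iron, phosphate and nitrate responses, glucosinolates and aquaporins. Clock genes of dawn and dusk and heat shock proteins served as signs of handling. Root hair, endodermis, xylem, phloem, meristem and photosynthetic shoot genes served as markers of cell types. The jasmonate and touch lists were included partly from general knowledge of what the study was about, and no member was chosen on these arrays. Lists were tested with camera at its preset correlation of 0.01 between genes, adjusted over the 27 lists. Camera with an estimated correlation, fry, and an exact two-sided permutation test of the list mean per array were run beside it. With 5 arrays against 5, the smallest p that this exact permutation test can give is 0.0079.

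The rule named every member of the mitochondrial calcium uptake list, the called genes with a reference symbol and no overlap between the groups (up to 8 in each direction), and up to 3 called members of each list or else the member of smallest p. Where no gene passed in a direction, the 4 genes of smallest p were named as not passing.

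The alternatives planned were dropping the dimmest 30% of genes, cyclic loess, centring each array on respiratory chain and tricarboxylic acid cycle genes, a trended and robust prior, array weights, the replicate number as a block, each array left out in turn, and a test against a minimum log2 change of 0.5. A fit without the 3 arrays of lowest weight was added after seeing the data. Scan dates and array batches were not given in the sources used here, so no batch could be tested.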

Results

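Root transcript levels of the mcu123 knockout were compared with those of the Col-0 wild type on 5 arrays per genotype, to ask which transcripts differ when MCU genes are disrupted. Arrays of one genotype correlated at 0.966 to 0.991 and arrays of different genotypes at 0.969 to 0.990 over all genes. No 2 arrays held identical values. One array, mcu123 replicate 3, lay apart from the rest along the first principal component, which held 25.7% of the variance, and had the lowest array weight (0.39).

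The targeted genes were examined first. MCU3 (AT2G23790) fell from 6.12 ± 0.22 in the wild type to 4.14 ± 0.28 in mcu123 (log2 intensity, mean ± SD, n = 5 each), a level 3.96-fold lower (limma adjusted p = 4.0e-04). MCU1 (AT1G09575) fell from 4.52 ± 0.23 to 2.87 ± 0.16, a level 3.15-fold lower (limma adjusted p = 4.0e-04). In every mcu123 array both genes lay below every wild-type array. MCU2 (AT1G57610) measured 2.86 ± 0.29 in the wild type and 2.77 ± 0.27 in mcu123, below the array median of 4.30 in both, and the difference of -0.09 (95% interval -0.46 to 0.27) was within the spread between arrays. The positions of the probes relative to the insertions are not given in the sources used here, so the MCU2 row checks nothing about that allele.

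**Figure D1:**
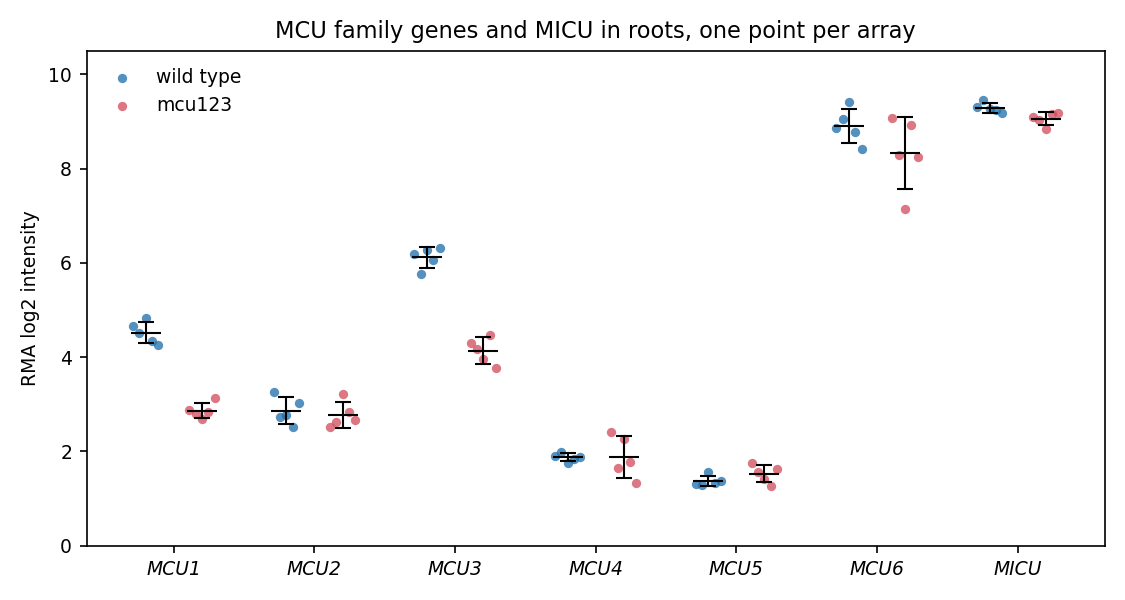
RMA log2 intensity (vertical axis) of the MCU family genes and MICU in wild-type (blue) and mcu123 (red) roots. Each point is 1 array, the bars give the mean ± SD of 5 arrays, and MCU1 and MCU3 passed the test, at 2.87 and 4.14 in mcu123 against 4.52 and 6.12 in the wild type. The arrays of MICU did not overlap between the genotypes either, by a narrow margin (9.172 against 9.176).

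The other genes of mitochondrial calcium uptake did not pass the test. MICU, the regulatory subunit of the uniporter, measured 9.29 ± 0.11 in the wild type and 9.06 ± 0.14 in mcu123 (n = 5, limma adjusted p = 0.69), and its groups did not overlap, with the highest mcu123 array at 9.172 and the lowest wild-type array at 9.176. MCU6 measured 8.91 ± 0.37 and 8.34 ± 0.76 (limma adjusted p = 0.75), with mcu123 replicate 3 lowest at 7.15, and a log2 difference of -0.57 that was -0.27 without that array. MCU4 and MCU5 lay under 2 on the log2 scale in both genotypes. The log2 differences of LETM1, LETM2 and GLR3.5 were 0.20, -0.16 and 0.06. As a list of 10 genes, mitochondrial calcium uptake had a mean log2 fold change of -0.43 and passed camera (adjusted p = 0.0010), with adjusted p = 0.086 with an estimated correlation. Its 2 members that fell, over all genes and adjusted over the list alone, were the targeted MCU1 and MCU3.

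Beyond the targeted genes, a small set of transcripts was lower in mcu123. The neighbouring annexin genes ANNAT4 (AT2G38750) and ANNAT3 (AT2G38760), which encode calcium-dependent membrane-binding proteins, fell by 1.59 (SE 0.20) and 1.54 (SE 0.20) on the log2 scale (limma adjusted p = 0.016 and 0.018). Both passed in 11 of 17 refits, and did not pass without wild type replicate 1, 3 or 4 or mcu123 replicate 4 or 5. MSRB7 (AT4G21830), a methionine sulfoxide reductase, fell by 1.53 from 10.25 ± 0.39 to 8.72 ± 0.44 (limma adjusted p = 0.045). It passed in 4 of 17 refits (limma adjusted p up to 0.19), and of those with 1 array left out it passed only without mcu123 replicate 3. JOX4 (AT2G38240), an oxidase that inactivates jasmonate, fell by 1.36 (SE 0.20) from 4.96 ± 0.30 in the wild type (limma adjusted p = 0.044). It passed in 5 of 17 refits (up to 0.24), and of those with 1 array left out only without mcu123 replicate 4.

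The other called genes fell outside the naming rule, since the reference gives them no symbol, and were chosen after their values were seen. AT4G29930 fell by 1.98, AT5G12010 by 1.64, AT1G36920 by 1.63, AT1G50970 by 1.62 and AT1G16670 by 0.97 on the log2 scale. AT1G36920 lay near the bottom of the scale in mcu123 (1.43), so the size of its fall is poorly bounded. AT4G29930 passed in all 17 refits, AT1G50970 in 16, AT1G36920 in 15 of 16, AT5G12010 in 6 and AT1G16670 in 5. AT5G58510 rose by 0.71 (SE 0.10), from 6.09 ± 0.14 to 6.80 ± 0.08, and was the single called gene that was higher in mcu123 (limma adjusted p = 0.044). It passed in 6 of 17 refits (limma adjusted p up to 0.32), and of those with 1 array left out only without wild type replicate 2 or mcu123 replicate 3. No gene with a symbol passed the test upward. The nearest by p were HDG7 (log2 difference 0.66), ATK4 (0.69), RABH1e (0.61) and NSP5 (0.62), at limma adjusted p-values of 0.096, 0.096, 0.11 and 0.14.

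In total 12 of 27826 genes changed, 1 higher and 11 lower in mcu123, and 10 of them, all lower, changed at least 2-fold. In all 12 the groups did not overlap. Over all genes 474 had groups that did not overlap, 190 higher and 284 lower, where chance gives 0.79% of genes, or 221. At an unadjusted p under 0.05 there were 2076 genes, where chance gives 1391. Both chance values are averages, and such counts can vary widely where genes vary together. Their spread was not examined, so neither excess was tested. The count of 12 was 5 without wild type replicate 1, wild type replicate 3 or mcu123 replicate 5, 6 without wild type replicate 4 or mcu123 replicate 4, 7 without mcu123 replicate 2 and 22 without mcu123 replicate 3. It was 3 without the 3 arrays of lowest weight, a fit added after seeing the data.

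Genes of the jasmonate pathway were lower in mcu123. In the jasmonate signalling and turnover list, 22 of 26 members had lower means and the mean log2 fold change was -0.69. JOX4 alone fell over all genes, a call kept in 5 of 17 refits, and 14 members fell adjusted over the list alone, 11 to 15 with each array left out and 5 without the 3 arrays of lowest weight. These 14 included the transcription factor MYC2 (log2 fold change -0.87), the JAZ repressors JAZ9 (-1.39), JAZ10 (-1.35), JAZ2 (-1.11) and JAZ12 (-0.79), and the oxidase JOX2 (-1.64, limma adjusted p = 0.065 over all genes). VSP1 and VSP2, jasmonate-responsive storage proteins, lay near the bottom of the scale in both genotypes, with log2 differences of 0.37 and 0.05.

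The jasmonate synthesis list had a mean log2 fold change of -0.55, with 11 of 13 members lower. No member fell over all genes, and 5 fell adjusted over the list alone: the lipoxygenases LOX3 (-1.33) and LOX4 (-1.22), the allene oxide synthase AOS (-0.97), the cyclase AOC3 (-0.66) and the reductase OPR3 (-0.83). The count of 5 was 3 without wild type replicate 1, 2 or 3 or mcu123 replicate 1, 2, 3 or 5, and 2 without the 3 arrays of lowest weight. LOX2, AOC1 and ACX1 had log2 differences of 0.06, 0.08 and -0.09. Every mcu123 array had a lower list mean than every wild-type array, at most 5.92 against at least 5.996 (exact permutation p = 0.0079, the smallest possible, adjusted p = 0.11).

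All 16 members of the touch and calcium-binding rapid response list had lower means in mcu123, with a mean log2 fold change of -0.62. No member fell over all genes, and 5 fell adjusted over the list alone: ZAT12 (-1.20), WRKY18 (-1.01), ERF6 (-0.77), the kinase MKK9 (-0.52) and the calmodulin gene TCH1 (-0.45). The count of 5 was 0 without wild type replicate 4, mcu123 replicate 3 or mcu123 replicate 5, 2 without wild type replicate 3, 3 without wild type replicate 2 or mcu123 replicate 2, and 11 without wild type replicate 5. It was 0 without the 3 arrays of lowest weight. TCH2 and TCH4, genes named for their response to touch, had log2 differences of -0.23 each.

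**Figure D2:**
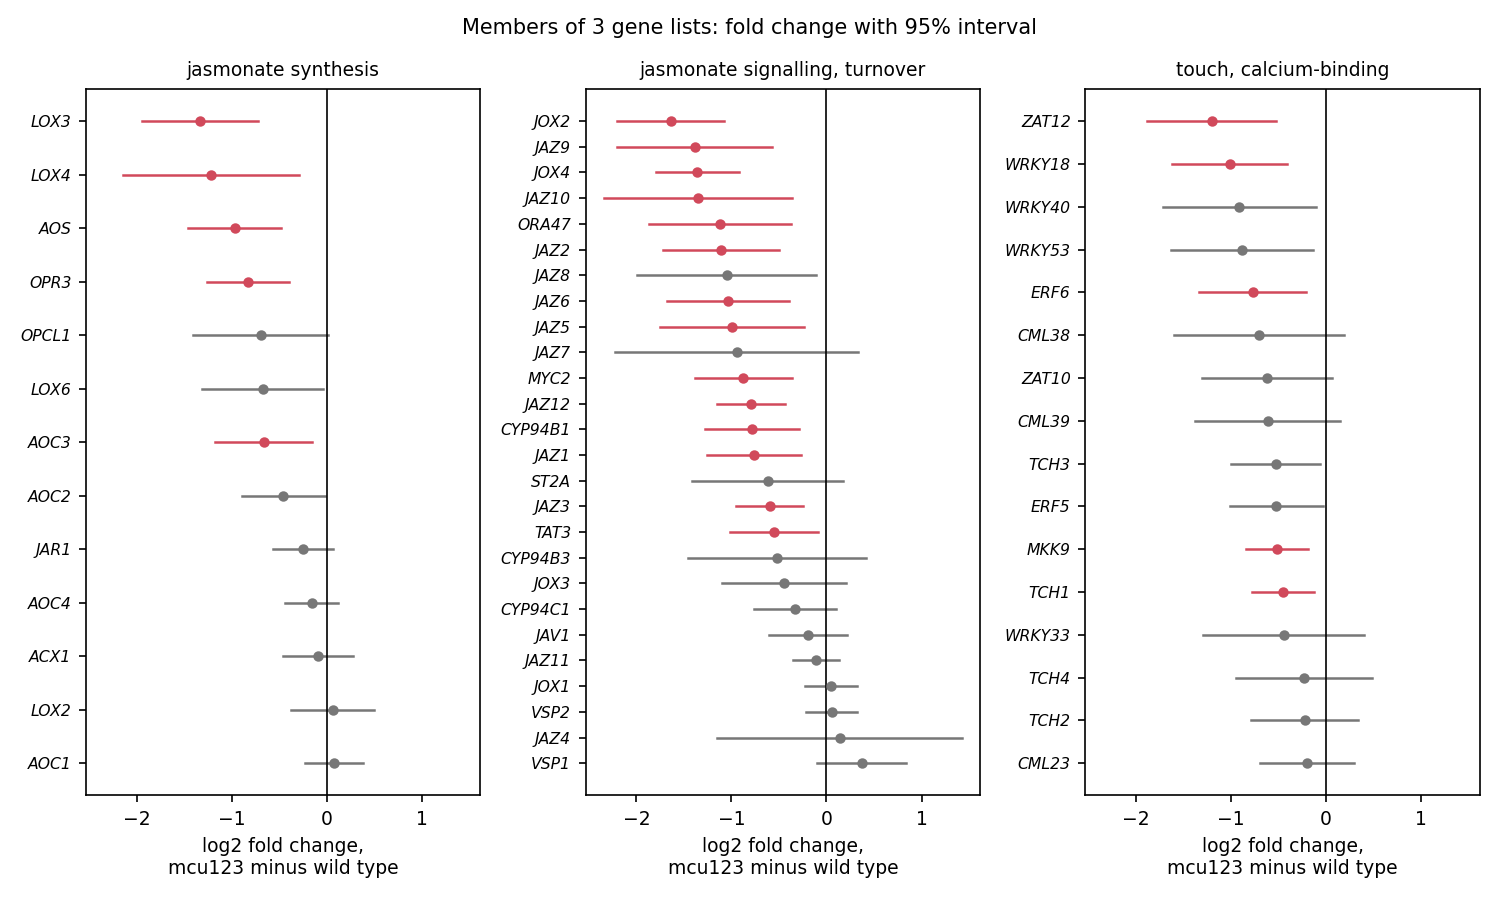
Log2 fold change of mcu123 minus wild type (horizontal axis) for each member of the jasmonate synthesis, jasmonate signalling and touch lists, with 95% intervals. Red marks members that passed adjusted over the list alone, 5 of 13, 14 of 26 and 5 of 16, and all red members lie below 0.

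These 3 lists passed camera at adjusted p-values of 1.5e-07 for synthesis, 4.3e-15 for signalling and 3.6e-10 for touch. With an estimated correlation the adjusted p was 0.086, 0.098 and 0.17, and none of the 27 lists passed. The groups overlapped for signalling, where wild type replicate 5 (5.14) lay at the level of the highest mcu123 arrays (5.14 and 5.22), and for touch (exact permutation p = 0.024 and 0.040, adjusted 0.21 and 0.26).

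Hypoxia-response genes were also lower as a list, with a mean log2 fold change of -0.36 and 11 of 13 members lower. No member fell over all genes, and 3 fell adjusted over the list alone: SUS4 (-1.02), a sucrose synthase, ADH1 (-1.03), alcohol dehydrogenase, and PCO1 (-0.69), a cysteine oxidase. The count of 3 was 0 without wild type replicate 3, mcu123 replicate 1 or mcu123 replicate 5, 1 without mcu123 replicate 2, and 5 without wild type replicate 5 or mcu123 replicate 3. The list passed camera (adjusted p = 9.4e-04), with adjusted p = 0.27 with an estimated correlation, and its array means overlapped between the groups (exact permutation p = 0.079). Among wild-type arrays, replicate 3 was highest and replicate 5 lowest for this list (5.15 and 4.21) and for touch (7.31 and 6.06). Among mcu123 arrays, replicate 3 was highest for hypoxia (4.65) but not for touch (6.05, with replicate 4 at 6.38). Handling at harvest was not tested for this list and stays open.

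Nuclear genes of the respiratory chain and ATP synthase were slightly higher in mcu123, with a mean log2 fold change of 0.14 and 32 of 39 members higher. No member passed, over all genes or adjusted over the list alone. The member of smallest p was CYC1-2, a cytochrome c1 gene, at 7.40 ± 0.11 and 7.71 ± 0.10 (n = 5, limma adjusted p = 0.48). The list passed camera (adjusted p = 2.3e-05), with adjusted p = 0.55 with an estimated correlation. Relative to the median of all genes the list lay 0.12 higher as deposited and with cyclic loess. Centring arrays on respiratory and tricarboxylic acid cycle genes brings the list near 0 by construction (-0.04) and moved the median of all genes to -0.17, which left the list 0.12 above that median. Without wild type replicate 2, the lowest array, the value was 0.09.

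**Figure D3:**
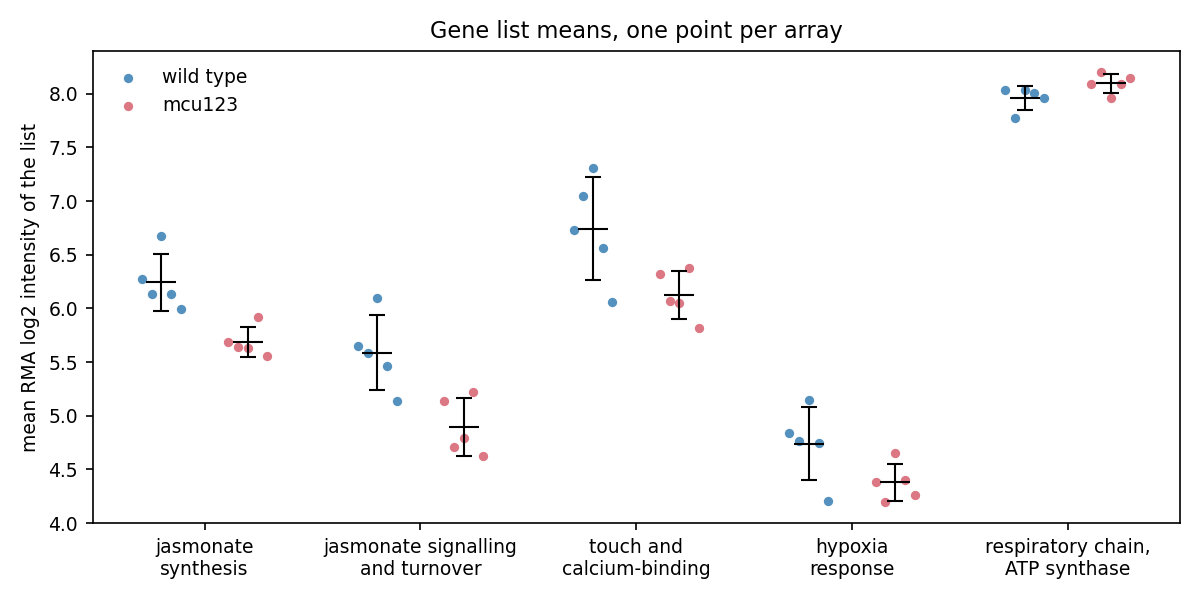
Mean RMA log2 intensity (vertical axis) of 5 gene lists in wild-type (blue) and mcu123 (red) roots. Each point is 1 array and the bars give the mean ± SD of 5 arrays, from 5.59 to 4.90 for jasmonate signalling and from 6.74 to 6.13 for touch, and the groups are fully apart for jasmonate synthesis only. The respiratory chain list went from 7.96 to 8.10, and centring on its own genes turns this to -0.04 by construction.

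In all, 6 of the 27 lists passed camera at its preset correlation, 3 passed fry and none passed the adjusted exact permutation test. The 3 by fry were mitochondrial calcium uptake (fry adjusted p = 3.5e-05), jasmonate synthesis (0.035) and jasmonate signalling (0.040). The smallest possible permutation p, 0.0079, was reached by 2 lists, mitochondrial calcium uptake and jasmonate synthesis. It gave an adjusted p of 0.11, so that test had little room to pass a list. Mitochondrial calcium uptake is among the 6, the 3 and the 2. Its only members that fell were the knocked-out MCU1 and MCU3, so its place there shows nothing beyond the knockout. Of 100 divisions of the 10 arrays into 5 and 5, the real one included, 28 gave as many lists at the preset correlation.

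The other 21 lists did not pass camera. Among mitochondrial and calcium lists, the mean log2 fold change was 0.08 for the tricarboxylic acid cycle (adjusted p = 0.16), 0.01 for alternative respiration and mitochondrial stress response (0.64) and -0.05 for calcium pumps, exchangers and channels (0.47). The members of smallest p were MMDH2, AT12CYS-2 and CAX1, with log2 differences of 0.40, 0.34 and 0.42. Among hormone and defence lists, it was -0.17 for salicylic acid (camera adjusted p = 0.26), -0.12 for glucosinolate and camalexin synthesis (0.27), 0.09 for auxin (0.49), -0.13 for abscisic acid (0.50) and 0.06 for cytokinin (0.50). Adjusted over the list alone, WRKY38 (-1.30) and CYP83B1 (-0.56) fell, and CYP71A13 (0.50) and HAI3 (0.47) rose at low levels. WRKY38 did not pass without wild type replicate 4 or mcu123 replicate 5, CYP83B1 and CYP71A13 without wild type replicate 3, and HAI3 without any one of 7 of the 10 arrays, passing only without wild type replicate 2 or 4 or mcu123 replicate 1. GH3.6 and ARR8, the members of smallest p in the auxin and cytokinin lists, had log2 differences of 0.44 (0.69 without mcu123 replicate 3) and 0.48. Without mcu123 replicate 3 the glucosinolate list was at -0.23 and passed camera (adjusted p = 0.021). It passed as well with array weights and without the 3 arrays of lowest weight.

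Among nutrient and water lists, the mean log2 fold change was 0.12 for nitrate (camera adjusted p = 0.39), 0.10 for iron deficiency (0.47), -0.02 for phosphate starvation (0.75) and 0.03 for aquaporins (0.64). The members of smallest p were NIA2 (0.54), S8H (0.44), PHT1;3 (0.43, and 0.22 without wild type replicate 2) and PIP2;5 (0.39). The nitrate and iron values took the other sign, -0.06 and -0.10, without mcu123 replicate 3, and the nitrate list was at 0.24 and passed camera without wild type replicate 2 (adjusted p = 0.0047).

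Markers of root cell types did not pass. The mean log2 fold change was 0.07 for root hair cells (camera adjusted p = 0.47), -0.09 for endodermis (0.27), -0.11 for xylem (0.27), 0.01 for phloem (0.64) and 0.02 for meristem and dividing cells (0.67), where the median (-0.07) and the test pointed down. CASP4 (-0.43), a Casparian strip protein, fell adjusted over the endodermis list alone, but not without wild type replicate 1 or 3 or mcu123 replicate 2, 4 or 5. EXPA7, IRX5, SUC2 and CYCB1;2 had log2 differences of 0.28, -0.31, -0.85 and -0.30. The SUC2 difference was -0.46 without mcu123 replicate 3, and that of EXPA7 was 0.17 without wild type replicate 5. In the fit without the 3 arrays of lowest weight, added after seeing the data, the root hair and xylem lists passed camera (adjusted p = 0.011 and 0.025).

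Genes of photosynthetic shoot tissue had a mean log2 fold change of 0.09 (camera adjusted p = 0.47), with the highest list mean, 3.29, in mcu123 replicate 5. This list passed camera without the 3 arrays of lowest weight (adjusted p = 0.011). RCA was at -0.23 (-0.12 without mcu123 replicate 3). Clock genes of dawn and of dusk had -0.15 (camera adjusted p = 0.27) and -0.10 (0.48), with CCA1 at -0.28 and GI at -0.51 (-0.33 without wild type replicate 2). Heat shock proteins had -0.12 (0.47), and the list was at -0.25 and passed camera without mcu123 replicate 3 (adjusted p = 0.023). DREB2A was at -0.62, and at -1.06 without wild type replicate 5 or -0.39 without wild type replicate 2.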

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

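All tests on mcu123 replicate 3 in this part were chosen after its values were seen. Of 152 sets of 5 arrays examined for an array far from the others, 13 were picked out, where chance gives about 7.6, and 7 of the 13 were mcu123 replicate 3. The values below in parentheses are the gap to the nearest array as a share of the range.

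In mcu123 replicate 3, genes of nutrient responses were higher than in the other mcu123 arrays. The list mean was 7.59 for nitrate (0.9072), where the other mcu123 arrays averaged 6.72 ± 0.04, and 4.30 for phosphate starvation (0.8676), where they averaged 3.82 ± 0.03. It was 5.33 for iron deficiency (0.7629), 4.68 for cytokinin (0.7284) and 5.45 for glucosinolates (0.8018), against 4.30, 3.92 and 4.93. Among the wild-type arrays, replicate 2 was highest for nitrate (mean 7.27) and phosphate starvation (mean 4.20), and lowest for iron deficiency (mean 4.01). SUC2, the phloem sucrose transporter, was at 3.23 (0.8191) against 5.16 ± 0.16, and GH3.6, an auxin conjugase, at 5.37 (0.825) against 6.61 ± 0.10. Among single genes picked after seeing the values, the nitrate transporter NRT2.1 was at 7.60 against 3.71, and the ammonium transporter AMT1;2 at 8.19 against 4.03. In the wild type NRT2.1 varied widely (SD 1.23). The sugar starvation-linked genes SEN1 and TPS11 were at 4.49 and 3.09 against 7.85 and 6.38. NIA1 of the nitrate list differed little, at 6.86 against 6.65 ± 0.53. In all, 1468 genes of this array differed at least 2-fold from the mean of the other mcu123 arrays, where the other 9 arrays had 106 to 646 against their own groups.

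A wild-type sample under a mutant label is argued against, since MCU1 and MCU3 of this array lay at -6.73 and -8.07 wild-type SDs from the lowest wild-type array. Carry-over of shoot tissue is argued against as well, since its photosynthetic list mean (2.52) was below the median of the other 4 mcu123 arrays (2.72). A difference in growth or nutrient state of that pool stays open and was not tested, and no biological explanation was tested. The counts with this array left out stand in the report.

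Of the wild-type arrays, replicate 2 was highest for the root hair list (6.38, 0.8642), CAX1 (5.47, 0.8249) and GI (9.52, 0.7193), and lowest for the respiratory chain list (7.77, 0.7292). Wild type replicate 4 was lowest for heat shock proteins (3.11, 0.804), and wild type replicate 5 was lowest for DREB2A (4.03, 0.7205).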

How the results depend on the processing

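The count of 12 changed genes was 7 with the dimmest genes dropped, 11 with cyclic loess, 24 centred on respiratory genes, 35 with a trended and robust prior, 30 with array weights, 3 in the test against a minimum change, and 5 to 22 with each array left out. The count at least 2-fold (10) was 6, 9, 23, 26 and 22 in the first 5 of these and 5 to 19 with each array left out. Without the 3 arrays of lowest weight, an alternative added after seeing the data, both counts were 3. The test against a minimum change called MCU1, MCU3 and AT1G50970. In the 17 refits against no change, MCU1, MCU3 and AT4G29930 passed in all. AT1G50970 passed in 16, AT1G36920 in 15 of 16, ANNAT3 and ANNAT4 in 11, AT5G12010 and AT5G58510 in 6, JOX4 and AT1G16670 in 5 and MSRB7 in 4. The 6 lists passed in all 17 refits at the preset correlation, while 0 lists passed with an estimated correlation, 3 with fry, and 11 without the 3 arrays. Adjusted over the list alone, the counts of 14 signalling, 5 synthesis and 5 touch members that fell were 16, 8 and 10 centred on respiratory genes, 15, 5 and 8 with a trended and robust prior, 13, 5 and 3 with array weights, and 5, 2 and 0 without the 3 arrays. With the replicate number as a block (replicate block), 8 genes were called, 7 of them among the 12. The values gave no sign that the numbers pair the arrays. Same-numbered arrays had deviations correlated at -0.21 to 0.09, and 0 arrays were closest to their own number. These values were not tested, so a growth batch shared by same-numbered arrays is not excluded. Centring on respiratory genes shifted the median of all genes to -0.17 and so turned small positive values negative: MCU5 -0.025, GLR3.5 -0.12, MCU4 -0.16, and the lists of respiratory chain -0.042, alternative respiration -0.16, tricarboxylic acid cycle -0.10, iron -0.075, nitrate -0.061, auxin -0.092, cytokinin -0.12, aquaporins -0.15, root hair -0.11, phloem -0.17, meristem -0.16 and photosynthetic tissue -0.085. Of these, the respiratory chain, iron and nitrate lists passed there (camera adjusted p = 0.0045, 0.039 and 0.039), still as higher than other genes. Dropping dim genes turned alternative respiration (-0.00607) and phloem (-0.011). Array weights turned GLR3.5 (-0.11), iron (-0.091), cytokinin (-0.064), abscisic acid (0.0198) and meristem (-0.032). Without the 3 arrays, GLR3.5 (-0.37), MCU4 (-0.00395), cytokinin (-0.15), abscisic acid (0.15), dusk clock genes (0.13), meristem (-0.069) and iron (-0.24, camera adjusted p = 0.010) turned. With each array left out, these ran across 0: MCU2 -0.20 to 0.00623, GLR3.5 -0.22 to 0.23, MCU4 -0.12 to 0.15, alternative respiration -0.00643 to 0.039, iron -0.10 to 0.20, phosphate -0.11 to 0.052, nitrate -0.059 to 0.24, cytokinin -0.091 to 0.13, aquaporins -0.00525 to 0.065, dusk clock genes -0.16 to 0.013, phloem -0.079 to 0.15, meristem -0.045 to 0.059 and photosynthetic tissue -0.041 to 0.16. Apart from the respiratory chain, none of these had passed in the analysis as reported. The cause was not tested except where fewer genes or arrays, or the centring itself, give it. With 1 row per gene and equal medians, using the mean of rows, every row, or median centring coincided with the analysis as reported. Signal over background was not given in the sources used here, so changes of dim genes such as MCU2 are poorly bounded.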

Other observations

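The tests of touch, clock genes and single arrays, of gene families and organelle genomes, and of neighbours among random genes were chosen after the results were seen. The divisions of the arrays and the windows around the MCU loci were set before.

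WRKY transcription factors, many of them linked to defence and wounding, mostly had lower means in mcu123, but no member passed over all genes. The family passed camera at the preset correlation only (exact permutation p = 0.0079, the smallest possible, adjusted p = 0.16). It shares members with the touch and salicylic acid lists, among them WRKY18 and WRKY38. Of 67 WRKY genes 48 had lower means, 18 were lower and 0 higher at an unadjusted p under 0.05, and the mean log2 fold change was -0.31. WRKY6 (-1.04) and WRKY48 (-1.50) came nearest to the threshold (limma adjusted p = 0.067 and 0.096). JAZ genes (mean -0.75, 9 of 10 lower), which overlap the jasmonate list, MPK kinases (-0.14, 17 of 20 lower), VPS genes (-0.10, 26 of 30 lower), CRK kinases (-0.16, 28 of 40 lower), MAPKKK kinases (-0.34, 11 of 13 lower) and GSTU glutathione transferases (-0.26, 20 of 27 lower) had the same direction, also with cyclic loess. EIF translation factors had a mean of 0.14, with 4 of 21 lower, and RPS genes 0.15, with 3 of 24 lower. Centring on respiratory genes moves all genes alike, to a median of -0.17, and so tests none of these directions: EIF and RPS were then at -0.04 and -0.03, but 0.12 and 0.14 above the median of all genes in both settings. Of 164 families of at least 10 numbered symbols, these 9 passed camera at the preset correlation and 0 with an estimated correlation. The adjusted p was then 0.30 for WRKY, JAZ, MPK, VPS, CRK and EIF, 0.55 for MAPKKK, 0.70 for GSTU and 0.87 for RPS.

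Transcripts of the mitochondrial genome were slightly higher in mcu123. The mean of 92 rows was 8.19 ± 0.08 in the wild type and 8.35 ± 0.07 in mcu123 (n = 5), with 12 rows lower (exact permutation p = 0.0079, the smallest possible, in 1 of 2 genomes examined). The groups were apart by a narrow margin, with mcu123 replicate 3 at 8.2402 and wild type replicate 3 at 8.2387. The estimated-correlation camera p was 0.018. The difference was 0.17 as deposited, 0.16 with cyclic loess and -0.01 centred on respiratory genes, a shift shared by all genes that left it 0.16 above their median in both. The array means followed those of the nuclear respiratory chain list. Wild type replicate 2 was the lowest array in both (8.05 and 7.77) and mcu123 replicate 2 the highest (8.43 and 8.20). Of the mcu123 arrays, replicate 3 was lowest in both (8.24 and 7.96). The 2 results are therefore not separate observations, and a difference between arrays shared by both was not tested. The 14 plastid rows differed by -0.05 (exact permutation p = 0.26).

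Chance division of the arrays was examined over 100 divisions into 5 and 5, the real one included. For the count of genes, 1 of 100 gave as many as the real 12, and the highest of the others was 0. For genes changed at least 2-fold, 1 of 100 gave as many as the real 10, and the highest of the others was 0. Chance can be excluded for both counts only as totals. Both include the knocked-out MCU1 and MCU3, which alone would exceed the other divisions. The divisions were not run without them, so chance is not excluded for the other called genes. For the lists, 28 of 100 gave as many as the real 6, and the highest of the others was 11. The real 6 include mitochondrial calcium uptake, which holds the knocked-out MCU1 and MCU3. Chance cannot be excluded for the number of lists past the threshold at the preset correlation.

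The jasmonate and touch lists were lower together in mcu123. Within genotypes, the list means of jasmonate signalling and touch varied together over the 10 arrays (r = 0.92, permutation p = 9.5e-04, adjusted 0.0019, rho = 0.89, permutation p = 0.0018, adjusted 0.0036), with r = 0.81 without the 2 arrays farthest out. For synthesis and touch r was 0.81 (permutation p = 0.018, adjusted 0.018, rho = 0.81, permutation p = 0.018, adjusted 0.018) and 0.54 without those 2 arrays. A single array is argued against as the cause. Without mcu123 replicate 3 the signalling difference was -0.66 against -0.69, and wild type replicate 3, the array that moved the lists most toward 0, left -0.56 for signalling, -0.44 for synthesis and -0.47 for touch. Handling at harvest is a candidate explanation: with the touch list mean as a covariate the signalling difference shrank to -0.22 (SE 0.11), within 2 standard errors of 0. The synthesis difference was -0.27 (SE 0.11) in the same fit, more than 2 standard errors below 0. These 2 remainders lay close together. A touch mean that tracks handling imperfectly leaves a remainder even under handling alone, so the fit does not decide for either list. Touch genes may themselves respond to genotype, so handling and genotype both stay open for signalling and synthesis. The dusk and dawn lists differed by -0.10 (95% interval -0.43 to 0.24) and -0.15 (-0.35 to 0.05). This excludes a time difference that moves them in opposite directions by over 0.3 each, and leaves open one that lowers both.

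Among the 50 genes of smallest p, 3 pairs were neighbours in the gene order of TAIR10.1: ANNAT4 with ANNAT3, JOX4 with AT2G38250, and AT1G36920 with AT1G36922, each lower in mcu123. By locus code, 2 of these pairs lie near each other on chromosome 2, AT2G38240 with AT2G38250 and AT2G38750 with AT2G38760. That chromosome also carries MCU3 (AT2G23790). The falls of JOX4, ANNAT4 and ANNAT3 may therefore not be separate observations, which was not tested. Random draws of 50 genes had a median of 0 pairs, and 0 of 10000 draws gave 3 (0.01% in a second set of 10000). Lists of 12, 25, 100 and 200 genes held 1, 2, 4 and 8 pairs, reached in at most 0.37% of draws. These lists are nested and each holds a pair seen before neighbours were counted, so they do not decide on random placement. Of the 3 pairs, 2 had been seen before neighbours were counted, and the 46 genes left without them held 1 pair, as did 7.18% of draws. Random placement and a linked segment both stay open. Windows around the disrupted loci held 0 of the 6 genes in these pairs, so they do not bear on the pairs: among the 20 genes on each side of MCU1, MCU2 and MCU3, 11 were at an unadjusted p under 0.05, against a median of 9 in random windows, and 29.0% of random sets had as many. Probes shared between related neighbours may contribute for the annexins and were not tested, since probe sequences were not used here.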
